A study of Homo sapiens with 4 samples.

How the data were processed

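Poly(A) RNA-seq libraries of the human erythroleukaemia line HEL were compared, 2 labelled Ctrl and 2 labelled AFF4 knockdown. Per the labels' protocols, RNA was captured on oligo(dT) beads and made into strand-marking libraries by the dUTP method, followed by PCR, with no molecular identifiers mentioned. The means of knockdown is not given in the sources used here. The labels call the libraries replicates and do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

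The deposited values were whole-number counts of reads per gene. Per the submitters' processing notes, the tools were fastp 0.13.1, HISAT2 2.1.0 and featureCounts 1.6.1 and the genome build hg38. The notes give no order or role for these tools, and the gene annotation, the strand setting and the treatment of multi-mapped reads are not given in the sources used here. These choices set how reads are split between paralogs, overlapping genes and antisense genes. The table held 28103 gene symbols, 9241 of them at 0 in all 4 libraries, with no entry for unassigned reads. The 4 value columns were matched to the samples by name, and 0 other columns were present. Total counts were 19129008 and 14903878 in Ctrl 1 and Ctrl 2 and 17955867 and 16643610 in knockdown 1 and 2. The 13 genes of the mitochondrial genome were not analysed here.

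Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its default settings (minimum count 10, minimum total count 15), which left 13572 genes, and libraries were scaled by TMM. This scaling treats most genes as unchanged, so all changes given here are relative to the other genes. A quasi-likelihood model with the group as the only term was fitted to all 4 libraries and tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and is said to have risen or fallen only then. The standard error was taken as the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.153. CPM values use the TMM-scaled library sizes and are given as mean ± SD of 2 libraries. With 2 libraries in each group, the precision rests on few degrees of freedom and on the spread shared across genes.

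Before the data were examined, 26 gene lists were fixed, covering the super elongation complex, the 7SK complex, pausing factors, stress and signalling responses, lineages, cell cycle, metabolism, ribosomal and histone genes, and markers of other cell types. AFF4 was left out of the test of its own complex. Lists with at least 5 tested members, 25 in all, were tested on log-CPM (prior count 2) with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The same lists were tested with an estimated correlation and with fry. Member counts come from the edgeR test, adjusted over all genes and again adjusted over the list alone. A list of NRF2 targets and the metallothionein family were added later.

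The genes named were chosen by a rule set before the data were examined. They are AFF4, any called member of the super elongation complex, 7SK or pausing lists, and the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and non-overlapping groups. To these were added, for each called list, the 3 members moving with the list that had the smallest adjusted p, and up to 2 that passed against it, and for other lists up to 3 members that passed. The 4 called genes without a usual symbol were counted and not named. Some genes that the rule takes are not reported here. Genes outside the rule are identified as such where they appear.

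Gene positions, exonic length, genomic span and transcript GC content came from the GENCODE v29 annotation of GRCh38, the assembly also called hg38, and not from the count table, which holds no lengths. Of the symbols, 25862 matched by name, 155 through a current symbol and 2086 had no match, and 97.4% of the tested genes had values. Relations to length and GC content are Spearman's rho across genes and medians in 5 equal-sized bins, without p-values.

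Alternatives planned beforehand were RLE, upper quartile and library-size scaling, no filter or a filter of at least 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. A GC correction, with and without the block, was added after the data were seen. It subtracts a lowess trend (span 0.4) of log-CPM on transcript GC content from each library and enters as an offset. A library left alone in its group was assumed to vary like the other group.

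The procedures were tested on simulated data. For counts drawn for 13459 genes with the means and sizes of these libraries, the edgeR test recovered 75% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, and called 22 unchanged genes. Unlike these libraries, the simulated counts had the same dispersion in both groups and no GC trend, so recovery in the data may differ. A GC trend was then added to 1 library (13440 genes). Its rho with GC content between the Ctrl libraries was 0.735, against 0.840 in the data. The GC correction raised the recovery of 2-fold changes from 28.3% to 68.7% and called 12 unchanged genes, against 0 before. A planted list of 40 genes was raised by 0.5 on the log2 scale. It had an adjusted p of 3.34e-21 by camera with the preset correlation, 0.156 with an estimated correlation and 0.0988 by fry. With the preset correlation 0 of 20 random lists were called. Genes were drawn independently of each other, so these simulations hold no correlation between genes.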

Results

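Poly(A) RNA was sequenced from HEL, a human erythroleukaemia line with erythroid and megakaryocytic features and an activated JAK-STAT pathway. The 4 libraries fall into 2 groups, Ctrl (wild-type genotype in the labels) and AFF4 knockdown, with 2 libraries in each. AFF4 is a scaffold of the super elongation complex, which brings the kinase P-TEFb to RNA polymerase II and promotes its release from promoter-proximal pausing. The title of the study names that release as its subject, and the comparison of the groups asks which steady-state transcripts differed when AFF4 was lowered. The summed gene counts were 19129008 in Ctrl 1, 14903878 in Ctrl 2, 17955867 in knockdown 1 and 16643610 in knockdown 2. The 10 most abundant genes took between 4.16% and 4.84% of the counts of a library.

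AFF4 (chromosome 5, 132875379 to 132963634, minus strand, hg38) fell in the knockdown. Its counts were 1650 and 1033 in the Ctrl libraries and 338 and 319 in the knockdown libraries. This corresponds to 78.7 ± 13.6 CPM in Ctrl and 18.8 ± 0.187 CPM in the knockdown (mean ± SD, n = 2 each). The log2 fold change was -2.07 ± 0.19 (SE; edgeR quasi-likelihood test, adjusted p = 0.0268). The fall was larger than the difference between the Ctrl libraries, and the sign matched the labels in each of the 4 pairs of a knockdown and a Ctrl library. With a stricter filter on low counts the edgeR adjusted p of AFF4 was 0.0552 and the call was lost, the highest adjusted p over 14 alternatives.

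The other subunits of the super elongation complex lay slightly higher in the knockdown as a list. Of the 12 tested members other than AFF4, 10 had a positive log2 fold change and 0 passed the edgeR test, adjusted over all genes or adjusted over the list alone (3 were higher at an unadjusted p under 0.05, and 0 passed in DESeq2 or limma-voom). The median was 0.28 (camera adjusted p = 0.0158 with the preset correlation; adjusted p = 0.353 with an estimated correlation). The AFF4 paralogs AFF1 and AFF2 had log2 fold changes of 0.42 ± 0.15 and 0.83 ± 0.29 (SE), and MLLT3, the AF9 subunit, had 0.44 ± 0.18, with edgeR adjusted p of 0.245, 0.258 and 0.310. The 9 genes of the 7SK complex that holds P-TEFb inactive had a median of -0.07 (camera adjusted p = 0.656), and the 25 pausing and elongation factors had a median of 0.03 (camera adjusted p = 0.610). Of these 2 lists 0 members passed edgeR, over all genes or adjusted over the list alone, DESeq2 or limma-voom, and at an unadjusted p under 0.05 the 7SK list had 0 and the pausing list 1 higher and 1 lower. The call of the super elongation complex list was lost without Ctrl 2, knockdown 1 or knockdown 2 (camera adjusted p = 0.0655, 0.0680 and 0.0556), and its median was 0.43 without Ctrl 1 and 0.17 with the stricter filter. MLLT3 ranged from 0.22 without Ctrl 2 to 0.70 without Ctrl 1. AFF2 ranged from 0.60 to 1.14 with 1 library left out and rests on few counts, 42 and 23 in Ctrl and 68 and 51 in the knockdown. In that list the Ctrl libraries also differed from each other, by a median of -0.25 in Ctrl 2 relative to Ctrl 1.

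**Figure D1:**
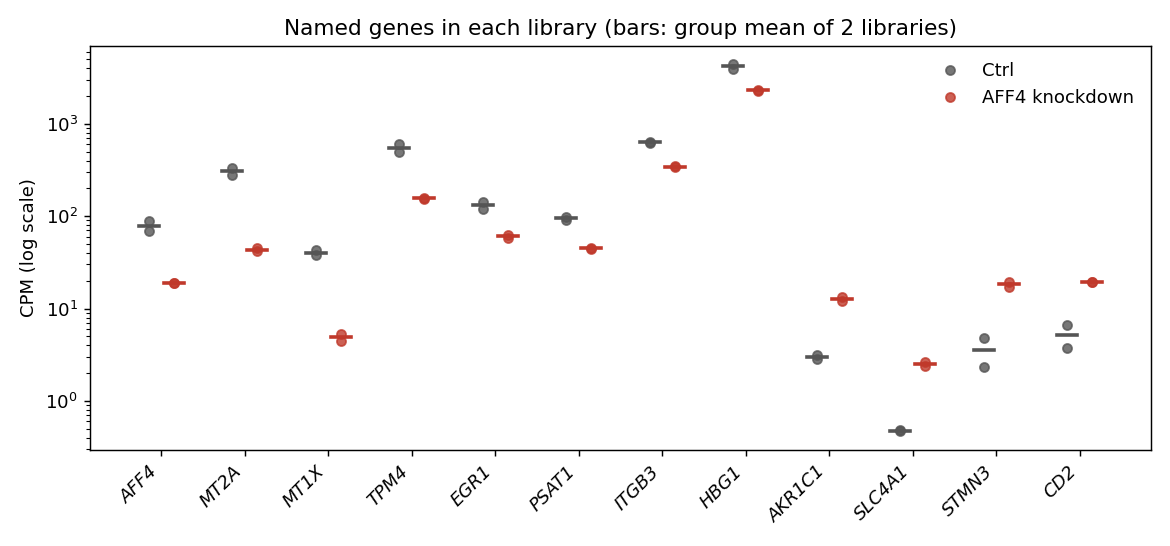
CPM on a log axis of 12 named genes in each library, with Ctrl in grey, AFF4 knockdown in red, 1 point per library and a bar at the mean of the 2 libraries. AFF4, MT2A, MT1X, TPM4, EGR1, PSAT1, ITGB3 and HBG1 were lower in both knockdown libraries than in both Ctrl libraries, and AKR1C1, SLC4A1, STMN3 and CD2 were higher in both.

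Across the transcriptome, the steepest falls among called genes with at least 5 CPM in Ctrl included those of metallothioneins, small cysteine-rich proteins that bind zinc and copper. MT2A fell from 306.5 ± 40.1 to 43.4 ± 2.57 CPM, MT1X from 40.3 ± 3.86 to 4.91 ± 0.641 CPM, MT1G from 24.1 ± 3.08 to 3.26 ± 0.0771 CPM and MT1E from 14.7 ± 0.457 to 3.43 ± 0.231 CPM (mean ± SD, n = 2 each). Their log2 fold changes were -2.82, -3.03, -2.88 and -2.09 (edgeR adjusted p = 0.00678, 0.00803, 0.0103 and 0.0268). These genes lie together on chromosome 16 (MT2A from 56608199 to 56609497, MT1X from 56682424 to 56684196). They are related paralogs of similar sequence, so the split of reads among them is uncertain. The other leading falls were those of ABCC3, an organic anion export pump, with a log2 fold change of -2.26, the creatine transporter SLC6A8 (-2.05), the stress-responsive transcription factor ATF3 (-2.01), the actin-binding tropomyosin TPM4 (-1.82) and the membrane metalloprotease ADAM9 (-1.72), each with an SE between 0.15 and 0.25. TPM4 was the most abundant of these, at 551.8 ± 78.1 CPM in Ctrl and 156.3 ± 3.31 CPM in the knockdown (n = 2 each).

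The leading rises came from lower levels. SLA, an adaptor that dampens receptor tyrosine kinase and antigen receptor signalling, rose from 0.971 ± 0.142 to 6.74 ± 0.626 CPM, and the microtubule-destabilizing stathmin STMN3 rose from 3.59 ± 1.74 to 18.4 ± 1.62 CPM (mean ± SD, n = 2 each). Their log2 fold changes were 2.78 ± 0.27 and 2.38 ± 0.33 (SE; edgeR adjusted p = 0.0268 and 0.0394). C2orf66 (2.32), the neurokinin B precursor TAC3 (2.30), the ubiquitin ligase TRIM6 (2.14) and the PDZ-domain protein PDZD2 (2.03) followed. The aldo-keto reductases AKR1C1 (chromosome 10, 4963253 to 4983283) and AKR1C2 (chromosome 10, 4987400 to 5018031), which reduce steroids and reactive carbonyls, had log2 fold changes of 2.08 ± 0.22 and 2.07 ± 0.29 (SE) and are similar enough to share reads. ISPD-AS1 also rose (2.28 ± 0.22), but it is an antisense gene and the strand setting of the counting is not given in the sources used here, so its reads are not separable from those of its partner.

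**Figure D2:**
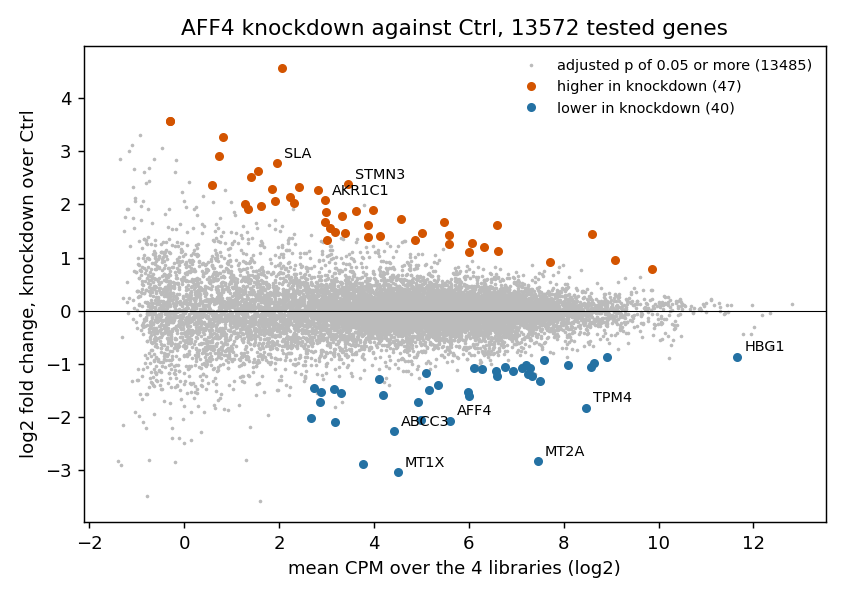
Log2 fold change of knockdown over Ctrl (vertical axis) against the mean CPM of the 4 libraries on a log2 scale (horizontal axis), 1 point per tested gene. The 47 genes that passed as higher are orange, the 40 that passed as lower are blue and the other 13485 are grey, with metallothioneins MT1X and MT2A among the lowest points.

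In all, 47 genes were higher and 40 lower in the knockdown among 13572 tested genes (edgeR adjusted p under 0.05), and 44 and 36 of them differed by at least 2-fold. The scaling of the libraries keeps the median log2 fold change near no change (-0.0089 over the tested genes). A rise or fall in RNA shared by all genes would therefore not show in these counts. All 87 had both knockdown libraries on the same side of both Ctrl libraries, a separation found in 46.1% of the tested genes and in 33.3% by chance. This count depended on the filter on low counts and on the libraries used. With the stricter filter 1 gene was higher and 4 lower, among them MT1X, MT1G, MT2A and TPM4, and the other called genes named here that were tested there lost their calls. With no filter 328 were higher and 406 lower, and in DESeq2 188 and 222. With library-size scaling EGR1, ALDH1L2, HIST1H1C and CD2 lost their calls. After removal of a trend with transcript GC content from each library, a correction chosen after the data were seen, 2273 genes were higher and 2312 lower, and all 87 genes were among them with the same sign. The count was 2986 higher and 3133 lower without Ctrl 1, 3407 and 3315 without Ctrl 2, 35 and 11 without knockdown 1, and 36 and 15 without knockdown 2. Of the 34 genes taken by the naming rule that passed, 19 passed in each of these leave-one-out fits. The calls of ATF3 and ADAM9 among the leading genes were lost, with an edgeR adjusted p of up to 0.0960 without knockdown 1 for ATF3 and up to 0.106 without either knockdown library for ADAM9.

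Genes of mitosis and the G2/M phase lay lower in the knockdown as a list. All 39 tested members had a negative log2 fold change, with a median of -0.55 (camera adjusted p = 6.64e-16 with the preset correlation; adjusted p = 0.353 with an estimated correlation). Over all genes 0 passed edgeR (34 were lower at an unadjusted p under 0.05, 8 passed in DESeq2 and 0 in limma-voom), whereas 32 fell when adjusted over the list alone and 39 fell after the GC correction. The cytokinesis scaffold ANLN was at 103.0 ± 22.3 CPM in Ctrl and 47.4 ± 2.21 CPM in the knockdown, the mitotic kinesin KIF2C at 386.2 ± 5.22 and 232.7 ± 2.03 CPM, and the proliferation marker MKI67 at 483.7 ± 28.5 and 307.4 ± 2.19 CPM (mean ± SD, n = 2 each). Their log2 fold changes were -1.12, -0.73 and -0.65 (edgeR adjusted p = 0.0636, 0.0641 and 0.0808). The Ctrl libraries differed in this list too, by a median of -0.32 in Ctrl 2 relative to Ctrl 1. The DNA replication list, which covers the S phase machinery, had a smaller median of -0.16 (46 tested, 35 negative; camera adjusted p = 0.0297; adjusted p = 0.375 with an estimated correlation). Among its members, RPA3, ORC1 and RFC5 had log2 fold changes of -0.66, -0.40 and -0.39, and 0 passed the edgeR test over all genes or adjusted over the list alone (3 were lower at an unadjusted p under 0.05, and 0 passed in DESeq2 or limma-voom). The DNA replication call was lost without Ctrl 1, knockdown 1 or knockdown 2 (camera adjusted p = 0.102, 0.119 and 0.163), with a median of -0.11 without Ctrl 1. RPA3 ranged from -0.91 to -0.35 with 1 library left out.

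Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median of -0.31 over 16 tested members (camera adjusted p = 0.0358; adjusted p = 0.353 with an estimated correlation). The linker histone HIST1H1C fell, from 105.6 ± 10.6 to 49.4 ± 1.46 CPM (n = 2 each; log2 fold change -1.10), and was also the 1 member that passed when adjusted over the list alone. HIST1H3G and HIST1H2BJ had log2 fold changes of -2.08 ± 0.55 and -0.53 ± 0.28 (SE) and did not pass. HIST1H3G rests on few counts, 13 and 16 in Ctrl and 5 and 2 in the knockdown. Most of the 16 tested histone genes lay under 5 CPM in both groups. The p53 target list had a median of -0.23 over 26 tested genes (camera adjusted p = 0.0144; adjusted p = 0.353 with an estimated correlation). It had 0 past the edgeR test over all genes (5 lower at an unadjusted p under 0.05, 3 in DESeq2 and 0 in limma-voom) and 3 that fell when adjusted over the list alone. Its members with the smallest adjusted p were TP53INP1 (-1.09), the cyclin-dependent kinase inhibitor CDKN1A (-1.54) and ZMAT3 (-0.86), with edgeR adjusted p of 0.0636, 0.101 and 0.112. The apoptosis and BCL2 family list had a median of -0.21 over 25 genes (camera adjusted p = 0.0358; adjusted p = 0.353 with an estimated correlation) and 0 members past the edgeR test over all genes or adjusted over the list alone (1 higher and 5 lower at an unadjusted p under 0.05, 0 in DESeq2 or limma-voom). In that list the death-promoting genes BMF, APAF1 and BCL2L11 had log2 fold changes of -0.67, -0.50 and -0.44. The histone call was lost without Ctrl 2 or knockdown 2 (camera adjusted p = 0.625 and 0.114), after the GC correction (0.142) and in limma-voom (0.0578). Its median was -0.11 without Ctrl 2 and -0.69 without Ctrl 1, and HIST1H2BJ ranged from -0.77 to -0.22 with 1 library left out. The p53 call was lost without Ctrl 1 or Ctrl 2 (0.102 and 0.0605), and the apoptosis call without Ctrl 1, knockdown 1 or knockdown 2 (0.112, 0.119 and 0.163) and with no filter (0.0575). Without Ctrl 1 the apoptosis median was -0.13. HIST1H1C lost its own call without either knockdown library (edgeR adjusted p of up to 0.654).

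Immediate early genes, which are induced within minutes of a stimulus and are often studied for paused polymerase, lay lower in the knockdown as a list. Of 30 tested members 25 were negative, 2 fell over all genes and 4 fell when adjusted over the list alone, with a median of -0.33 (camera adjusted p = 1.63e-04; adjusted p = 0.353 with an estimated correlation). ATF3 fell from 10.2 ± 1.01 to 2.53 ± 0.534 CPM, and the zinc-finger factor EGR1 fell from 131.6 ± 16.6 to 60.4 ± 3.31 CPM (mean ± SD, n = 2 each), a log2 fold change of -1.12 ± 0.16 (SE; edgeR adjusted p = 0.0415). KLF6 had -1.02 ± 0.21 and did not pass (edgeR adjusted p = 0.0901). Without Ctrl 2 the median of the list was -0.09 and its call was lost (camera adjusted p = 0.140), and the Ctrl libraries differed in this list by a median of 0.25 in Ctrl 2 relative to Ctrl 1. EGR1 lost its call without either knockdown library (edgeR adjusted p of up to 0.543), and ATF3 without knockdown 1 (0.0960).

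Genes of the ATF4 and unfolded protein response, which supply amino acids and folding capacity under stress, were also lower as a list, with 30 of 35 tested members negative and a median of -0.26 (camera adjusted p = 6.14e-06; adjusted p = 0.353 with an estimated correlation). Over all genes 3 fell, and 7 fell when adjusted over the list alone. Besides ATF3, which is also in this list, these were the serine synthesis enzyme PSAT1, from 94.6 ± 6.32 to 44.7 ± 1.10 CPM, and the mitochondrial folate enzyme ALDH1L2, from 11 ± 1.64 to 3.84 ± 0.195 CPM (n = 2 each). Their log2 fold changes were -1.08 ± 0.16 and -1.52 ± 0.22 (SE; edgeR adjusted p = 0.0415 and 0.0444). Both lost their calls without either knockdown library (edgeR adjusted p of up to 0.702 for PSAT1 and 0.332 for ALDH1L2), and ATF3 lost its call without knockdown 1 (0.0960). The heat shock list had a median of 0.06 over 21 genes (camera adjusted p = 0.583), with 0 past the edgeR test, DESeq2 or limma-voom and 1 higher at an unadjusted p under 0.05.

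The cholesterol synthesis list and the list of glycolysis and hypoxia genes, called the glycolysis list below, lay lower as well. In the cholesterol list 22 of 25 tested members were negative, with a median of -0.29 (camera adjusted p = 1.63e-04; adjusted p = 0.353 with an estimated correlation). INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, fell from 213.2 ± 19.7 to 101.4 ± 2.46 CPM (n = 2 each; log2 fold change -1.07), and 6 members fell when adjusted over the list alone. The synthesis enzyme MSMO1 had a log2 fold change of -0.93 and did not pass (edgeR adjusted p = 0.0808). In the glycolysis and hypoxia list 26 of 34 members were negative, with a median of -0.39 (camera adjusted p = 1.63e-04; adjusted p = 0.353 with an estimated correlation), 2 fell over all genes and 14 fell when adjusted over the list alone. The glucose transporter SLC2A3 fell from 527.8 ± 45 to 268.1 ± 1.40 CPM and the hypoxia-induced repressor BHLHE40 from 147.2 ± 11.8 to 70.9 ± 2.55 CPM (n = 2 each). The aldolase ALDOC had a log2 fold change of -0.80 and did not pass (edgeR adjusted p = 0.0997). Glycolytic enzymes of this list, named after their values were seen, did not move together. GPI, GAPDH and ENO1 had -0.60, -0.44 and -0.43, TPI1, PGK1 and PKM had -0.05, -0.10 and -0.09, and HK1 had 0.32. These enzymes did not pass the edgeR test over all genes. INSIG1, SLC2A3 and BHLHE40 lost their calls without either knockdown library (edgeR adjusted p of up to 0.654, 0.603 and 0.808). Nuclear-encoded OXPHOS genes had a median of -0.02 over 62 genes (camera adjusted p = 0.909), with 0 past the edgeR test, DESeq2 or limma-voom and 1 higher at an unadjusted p under 0.05.

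**Figure D3:**
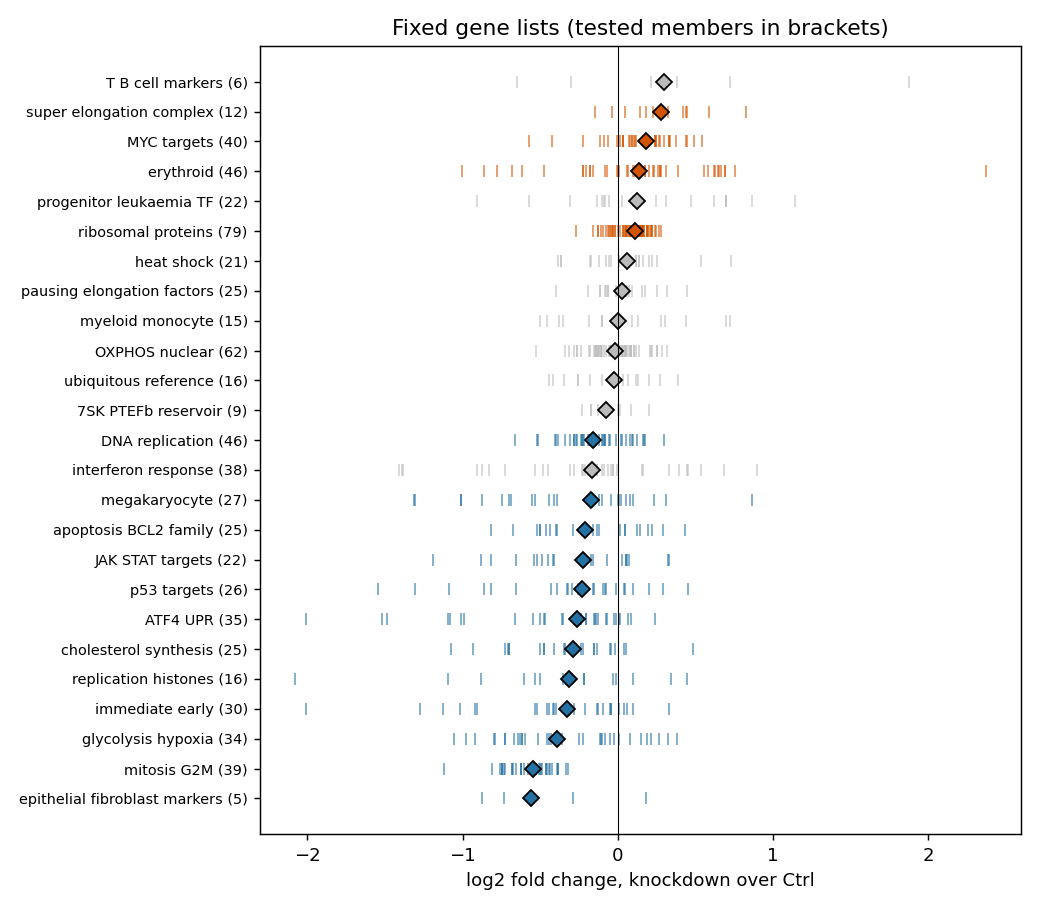
Log2 fold change of knockdown over Ctrl for the tested members of the 25 gene lists, with 1 tick per gene, a diamond at the median and the number of tested members in brackets. The 4 lists called higher by camera with the preset correlation are orange, the 12 called lower are blue and the others are grey, and the ticks of the mitosis list all lie below 0.

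Among the lineage lists, erythroid genes had a median of 0.14 over 46 tested members, 31 of them positive (camera adjusted p = 0.0358; adjusted p = 0.624 with an estimated correlation). Over all genes 1 rose and 1 fell, and adjusted over the list alone 8 rose and 6 fell. The anion exchanger of the red cell membrane, SLC4A1, rose from 0.475 ± 0.00938 to 2.50 ± 0.167 CPM, a low level, and the fetal globin HBG1 (chromosome 11, 5248079 to 5249859) fell from 4165 ± 329 to 2292 ± 69.7 CPM (n = 2 each). HBG1 is a near-identical copy of HBG2, so the split of reads between them is uncertain. HBG2, outside the naming rule, was also lower, at 6556 CPM in Ctrl and 4091 CPM in the knockdown. Its log2 fold change of -0.68 did not pass (edgeR adjusted p = 0.0641). These values argue against reads moving from HBG1 to HBG2 as the cause of the HBG1 fall. Of the other globins tested, also outside the rule, HBE1, HBA1 and HBA2 had -0.48, -0.23 and -0.18. HBZ went from 10.6 to 5.26 CPM, while HBB, HBD and HBQ1 had 0.0019, 0.65 and 0.15. The heme synthesis enzyme FECH had a log2 fold change of 0.69 and did not pass (edgeR adjusted p = 0.0872). The Ctrl libraries differed in the erythroid list by a median of 0.27 in Ctrl 2 relative to Ctrl 1, and its call was lost without Ctrl 1, knockdown 1 or knockdown 2 (camera adjusted p = 0.841, 0.0623 and 0.125). The erythroid median was 0.03 without Ctrl 1 and 0.36 without Ctrl 2. HBG1 lost its call without either knockdown library (edgeR adjusted p of up to 0.337), and SLC4A1 without knockdown 2 (0.0576).

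Megakaryocyte genes had a median of -0.17 over 27 tested members, 18 of them negative (camera adjusted p = 0.00291; adjusted p = 0.353 with an estimated correlation). Over all genes 3 fell, and adjusted over the list alone 6 fell and 1 rose. The platelet integrin ITGB3 fell from 626.9 ± 20.8 to 342.4 ± 3.28 CPM, the myosin light chain kinase MYLK from 197.7 ± 7.73 to 98.1 ± 3.72 CPM and the granule secretion GTPase RAB27B from 258.5 ± 61.9 to 103.9 ± 1.52 CPM (mean ± SD, n = 2 each). Their log2 fold changes were -0.87, -1.01 and -1.32 (edgeR adjusted p = 0.0415, 0.0394 and 0.0415). The JAK-STAT list had a median of -0.23 over 22 members (camera adjusted p = 0.00994; adjusted p = 0.375 with an estimated correlation). Besides target genes it holds components of the pathway, such as JAK2, STAT5A and STAT5B (-0.41, -0.07 and 0.03), so its median is not a measure of targets alone. Of its members 0 passed edgeR over all genes (1 higher and 7 lower at an unadjusted p under 0.05, 3 lower in DESeq2, 0 in limma-voom) and 6 fell when adjusted over the list alone. The kinases PIM1 and PIM2 and the feedback inhibitor SOCS3 had log2 fold changes of -0.88 ± 0.14, -0.66 ± 0.13 and -1.19 ± 0.21 (SE; edgeR adjusted p = 0.0519, 0.0808 and 0.0641). Without Ctrl 2 the megakaryocyte and JAK-STAT calls were lost (camera adjusted p = 0.165 and 0.134). The megakaryocyte median was -0.06 without Ctrl 2 and -0.30 without Ctrl 1, and the JAK-STAT median -0.13 and -0.45. Without either knockdown library, the edgeR adjusted p of ITGB3, MYLK and RAB27B reached 0.808, 0.820 and 0.222.

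MYC target genes and ribosomal protein genes lay slightly higher relative to the other genes. MYC targets had a median of 0.18, with 33 of 40 positive (camera adjusted p = 0.0169; adjusted p = 0.353 with an estimated correlation). The ribosome biogenesis genes MRTO4 and UTP20 and MYC itself had log2 fold changes of 0.44, 0.54 and 0.33 (edgeR adjusted p = 0.202, 0.209 and 0.275). Ribosomal proteins had a median of 0.11, with 63 of 79 positive (camera adjusted p = 0.0297; adjusted p = 0.353 with an estimated correlation). The members moving with the list that had the smallest adjusted p, RPS18, RPS23 and RPL15, had log2 fold changes of 0.28, 0.27 and 0.20. In both lists 0 passed edgeR, over all genes or adjusted over the list alone, DESeq2 or limma-voom, and at an unadjusted p under 0.05 the MYC list had 4 higher and 2 lower and the ribosomal list 0. The MYC call was lost without Ctrl 1, knockdown 1 or knockdown 2 (camera adjusted p = 0.306, 0.0754 and 0.121), with a median of 0.05 without Ctrl 1 and 0.30 without Ctrl 2. RPS23 ranged from 0.12 to 0.42 with 1 library left out. The ribosomal call was lost without Ctrl 2, knockdown 1 or knockdown 2 (camera adjusted p = 0.177, 0.296 and 0.132).

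Among the remaining lists, the interferon response list had a median of -0.16 over 38 genes and was not called (camera adjusted p = 0.0764). Its member OAS3, an antiviral oligoadenylate synthetase, fell from 58.7 ± 6.92 to 22.5 ± 0.131 CPM (n = 2 each; edgeR adjusted p = 0.0379), and 5 members fell and 2 rose when adjusted over the list alone. The interferon list was called lower without Ctrl 2 or knockdown 1 (camera adjusted p = 0.0442 and 0.0277), with no filter (0.0233) and after the GC correction (0.0495). Without Ctrl 1 its median was -0.07 (camera adjusted p = 0.679). Progenitor and leukaemia transcription factors had a median of 0.12 (0.09 without Ctrl 1 and 0.22 without Ctrl 2; camera adjusted p = 0.0697), with 0 past the edgeR test over all genes or in limma-voom, 1 higher in DESeq2, 5 higher and 2 lower at an unadjusted p under 0.05, and 1 higher and 1 lower when adjusted over the list alone. Myeloid and monocyte genes had a median of 0.00096 (-0.14 without Ctrl 1 and 0.23 without Ctrl 2; camera adjusted p = 0.656) and widely expressed reference genes -0.02 (camera adjusted p = 0.696), with 0 past edgeR, DESeq2 or limma-voom in each. At an unadjusted p under 0.05, 3 myeloid genes were higher, and 1 reference gene was higher and 1 lower. Markers of cells that the culture should not hold were also tested. Of these, 6 of 17 T and B cell markers and 5 of 16 epithelial and fibroblast markers passed the filter on low counts. Which cells their transcripts came from was not tested. In the list of T and B cell markers 6 genes were tested (camera adjusted p = 0.209) and CD2, an adhesion receptor of T cells, rose from 5.19 ± 2.04 to 19.3 ± 0.153 CPM (n = 2 each; edgeR adjusted p = 0.0471). CD4, the most abundant tested member and named after its values were seen, was at 129.6 ± 11.1 CPM in Ctrl and 82.7 ± 2.26 CPM in the knockdown, a log2 fold change of -0.65 ± 0.15 (SE) that did not pass over all genes (edgeR adjusted p = 0.109). Adjusted over the list alone 1 rose and 1 fell, and 1 was higher and 1 lower in DESeq2. This list was called higher without Ctrl 2 or knockdown 1 (camera adjusted p = 0.0442 and 0.0101). The epithelial and fibroblast list had a median of -0.56 over 5 tested genes (camera adjusted p = 0.0297; adjusted p = 0.353 with an estimated correlation). THY1, KRT8 and PDGFRB had log2 fold changes of -0.88, -0.73 and -0.56. Of its members 0 passed edgeR over all genes (2 lower at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom) and 2 fell when adjusted over the list alone. Its call was lost without Ctrl 1, Ctrl 2, knockdown 1 or knockdown 2 (camera adjusted p = 0.112, 0.0669, 0.0829 and 0.0556) and with no filter (0.0701). Its median was -0.27 without knockdown 1, and PDGFRB ranged from -0.90 to -0.25 with 1 library left out. OAS3 lost its call without either knockdown library (edgeR adjusted p of up to 0.398).

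Across the lists, 16 of 25 were called by camera with the preset correlation, 4 higher and 12 lower. With an estimated correlation 0 were called (lowest adjusted p = 0.353, with 2 lists at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move one way on balance, called 0 (lowest adjusted p = 0.0852, with 11 at an unadjusted p under 0.05). The mitosis, ATF4, cholesterol and glycolysis lists kept their camera call in each of the leave-one-out fits. After the GC correction 4585 of all 13572 tested genes passed the edgeR test, which is the background for the members that then passed in each list. In the super elongation complex list 7 of 12 rose and 0 fell, and in the MYC list 22 of 40 rose and 3 fell. In the erythroid list 22 of 46 rose and 9 fell, and in the ribosomal list 15 of 79 rose and 1 fell. In the heat shock list 8 of 21 rose and 1 fell. In the ATF4 list 0 of 35 rose and 21 fell, and in the cholesterol list 1 of 25 rose and 16 fell. In the glycolysis list 5 of 34 rose and 18 fell, and in the DNA replication list 1 of 46 rose and 20 fell. The megakaryocyte list then had 2 of 27 that rose and 10 that fell, the JAK-STAT list 2 of 22 and 11, and the immediate early list 1 of 30 and 10. The p53 list had 3 of 26 that rose and 8 that fell, the apoptosis list 3 of 25 and 10, and the interferon list 6 of 38 and 12. In the progenitor list 7 of 22 rose and 3 fell, and in the OXPHOS list 8 of 62 rose and 4 fell. In the myeloid list 4 of 15 rose and 2 fell, and in the pausing list 3 of 25 rose and 2 fell. In the reference list 2 of 16 rose and 5 fell, and in the 7SK list 1 of 9 rose and 1 fell. The T and B cell list had 2 of 6 that rose and 1 that fell, the histone list 0 of 16 and 2, and the epithelial and fibroblast list 0 of 5 and 3.

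The log2 fold change had no clear relation to gene length. Across 13218 genes, Spearman's rho with exonic length was -0.0045 and that with the genomic span of the gene 0.021, where genes are not independent replicates. Taken by single pairs of a knockdown and a Ctrl library, rho with exonic length lay between -0.084 and 0.077 and rho with span between -0.172 and 0.211. Both were negative against Ctrl 1 and positive against Ctrl 2, so the direction depended on the Ctrl library. The median log2 fold change of the 5 bins of span lay between -0.03 and 0.01.

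The Ctrl libraries stood apart from each other. The SD over genes of the log2 difference was 0.49 between the Ctrl libraries and 0.23 between the knockdown libraries, and the difference had a Spearman's rho with transcript GC content of 0.840 in Ctrl and 0.419 in the knockdown across genes. From the lowest to the highest of 5 bins of GC content the median of Ctrl 2 relative to Ctrl 1 went from -0.41 to 0.68. The first principal component, with 54.9% of the variance, separated the groups, and the next, with 38.1%, separated Ctrl 1 from Ctrl 2. In both groups the counts of the 2 libraries differed by more than counting noise (chi-square per degree of freedom 44.3 in Ctrl and 2.50 in the knockdown), which shows only that neither pair is the same counts deposited again, and the spread may still be technical.

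**Figure D4:**
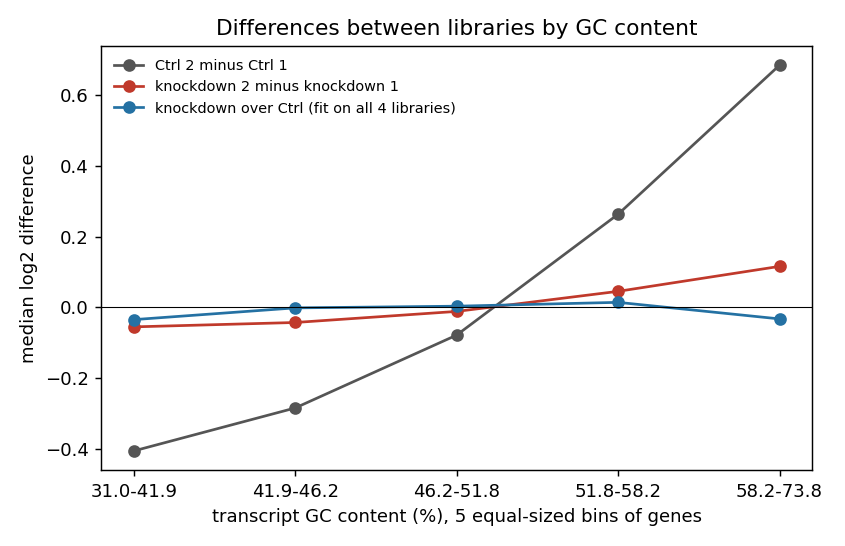
Median log2 difference (vertical axis) in 5 equal-sized bins of genes by transcript GC content in percent (horizontal axis), for Ctrl 2 relative to Ctrl 1 in grey, knockdown 2 relative to knockdown 1 in red and the fitted knockdown over Ctrl in blue. The grey line climbs from -0.41 to 0.68, while the blue line stays between -0.03 and 0.01.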

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

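The GC correction, with and without the block, was added after the data were seen, and all other alternatives were planned. All 87 called genes kept their sign wherever they were tested, and the AFF4 log2 fold change lay between -2.23 and -1.88 in 14 alternatives, past the threshold in 13, with -2.10 and an edgeR adjusted p of 0.0552 under the stricter filter, where fewer genes were tested. Higher and lower genes numbered 328 and 406 with no filter, 1 and 4 with the stricter filter, 188 and 222 in DESeq2, 2273 and 2312 with the GC correction, and 1 and 2 at an adjusted p under 0.01. Leaving out 1 library gave between 35 and 3407 higher and between 11 and 3315 lower genes. RLE, upper quartile and library-size scaling and limma-voom stayed within 1.5 times of 47 and 40. The cause of these shifts was not tested, except that leaving out a Ctrl library removes the spread between the Ctrl libraries.

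With the replicate block 408 genes were higher and 480 lower, and with the block and the GC correction 2770 and 2758. The block lost the camera calls of the MYC, erythroid and ribosomal lists (camera adjusted p = 0.0739, 0.0679 and 0.167). Those of the DNA replication and apoptosis lists were lost too (camera adjusted p = 0.105 each), and the interferon list was called lower (0.0472). Replicate numbers did not pair the samples by the labels, and with 2 pairs the correlation of their deviations was 0.285, or 0.0933 after the GC correction.

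Lists called higher numbered 4 in the fit to all libraries, 1 with the replicate block, between 0 and 3 with 1 library left out, 0 at an adjusted p under 0.01, and 0 with an estimated correlation or fry. Lists called lower numbered 12, between 7 and 10 with 1 library left out, 7 at an adjusted p under 0.01, and 0 with an estimated correlation or fry. With 2 libraries per group these tests have little power, as the planted list showed (adjusted p = 0.156 and 0.0988). Its genes were drawn independently, so the simulation does not cover lists whose genes vary together. In the data the estimated correlation lay between -0.042 in the progenitor list and 0.344 in the mitosis list. Where it exceeds the preset 0.01, p-values with the preset correlation may be too small. Low power and such correlation cannot be told apart as reasons for the lost calls. Small lists fell under 5 members with the stricter filter and gave no value there. The rank correlation of log2 fold change with exonic length lay between -0.083 and 0.073 with 1 library left out, and that with genomic span was 0.021. SLC4A1, at 0.475 CPM in Ctrl, rests on few counts and was not tested under the stricter filter.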

Other observations

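The genes in this paragraph were chosen from the calls after their values were seen, and no list of such genes was tested. CPA3, a mast cell protease, rose from 47.5 ± 11.1 to 145.4 ± 1.76 CPM, the prostaglandin D synthase HPGDS from 9.59 ± 1.82 to 25.5 ± 1.62 CPM, and HPGD, which inactivates prostaglandins, from 210.0 ± 35.2 to 570.5 ± 12 CPM (mean ± SD, n = 2 each; edgeR adjusted p = 0.0356, 0.0471 and 0.0274). PRG2, the eosinophil granule major basic protein, went the other way, with a log2 fold change of -1.07 (edgeR adjusted p = 0.0387). The checkpoint ligand CD274 fell from 52.4 ± 8.37 to 18.8 ± 1.19 CPM and the lysosomal thiol reductase IFI30 from 9.69 ± 0.977 to 3.56 ± 0.262 CPM (edgeR adjusted p = 0.0387 and 0.0472). Pyruvate kinase PKLR, catalase CAT and transferrin TF rose, with log2 fold changes of 1.47, 0.92 and 1.12 (edgeR adjusted p = 0.0394, 0.0415 and 0.0387).

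Of the tests below, the GC test of the Ctrl difference was chosen only after the result was seen. The Ctrl libraries differed from each other more than the knockdown libraries did. Removing the GC trend lowered the SD of the Ctrl difference to 0.573 of its value. The trend was fitted to these same libraries, so this restates the relation to GC content and is not separate support for a GC bias. An excess of non-coding RNA in Ctrl 2 was tested with protein-coding genes alone, whose SD was 0.979 of that over all tested genes. The Ctrl difference was thus present among protein-coding genes, and non-coding genes alone do not account for it. This ratio cannot show whether Ctrl 2 held more non-coding RNA, since it need not change with such an excess. RN7SK, chosen after its values were seen, was at 26.8 CPM in Ctrl 2 and between 4.07 and 4.99 CPM in the other libraries. What remains of the Ctrl difference was not explained, and a difference in culture was not tested.

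The mitosis median was -0.54 after the GC correction. The fitted log2 fold change already had almost no relation to GC content (rho -0.0038). The correction could therefore hardly move this median and does not test GC bias. Single pairs had a rho with GC content of 0.41 and 0.50 against Ctrl 1 and -0.51 and -0.41 against Ctrl 2. The mitosis median was -0.72 without Ctrl 2 and -0.43 without Ctrl 1, negative under both GC trends, a comparison made after the values were seen. These leave-one-out medians argue against GC bias and against a high level in Ctrl 1 alone as the whole cause. Fewer cycling cells in the knockdown is a hypothesis that stays open. The median of the DNA replication list after the GC correction was -0.140, against -0.54 for the mitosis list. The interquartile range of its members divided by the square root of their number, which treats genes as independent, was 0.0346. With that margin the DNA replication median lay between the bounds set beforehand for and against that hypothesis. Fewer cycling cells and a change specific to G2/M genes therefore cannot be told apart here. Cell numbers and cell cycle phases were not analysed here.

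Of the 12 metallothionein genes counted, 7 were tested and the other 5 did not pass the filter on low counts. All 7 were negative, of which 4 fell (6 after the GC correction), while MT1F, MT1L and MT1JP did not pass. Reads moving between paralogs are argued against as the cause, since the summed CPM of the family changed by -2.77 on the log2 scale, between -2.92 and -2.61 in the 4 pairs of libraries. A candidate explanation is lower metal-responsive transcription through MTF1. Its target SLC30A1, a zinc exporter, had a log2 fold change of -1.06 ± 0.21 (SE), from 14.6 ± 1.83 to 6.98 ± 0.374 CPM, which goes with that hypothesis but rests on 1 gene that did not pass on its own (edgeR adjusted p = 0.0797; 3.7e-04 after the GC correction). Zinc in the medium was not analysed here, and a direct effect of AFF4 on these genes was not tested.

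AKR1C3, chosen after its values were seen, rose with AKR1C1 and AKR1C2 (log2 fold change 1.61 ± 0.19, SE; edgeR adjusted p = 0.0356), and these genes are known targets of NRF2. A broad NRF2 response was tested as a hypothesis and is argued against, since the 24 other NRF2 targets tested had a median of -0.145, with 6 positive and 0 past edgeR, DESeq2 or limma-voom (1 higher and 2 lower at an unadjusted p under 0.05 in edgeR; camera p = 0.0808 with the preset correlation).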
